A study of Camellia sinensis with 12 samples.

How the data were processed

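Leaf RNA of 4 tea genotypes was profiled by RNA sequencing, with 3 libraries per genotype and 12 in all. Per the labels, Kucha-6 (K6) and Kucha-11 (K11) are Kucha genotypes, and Yinghong 9 (YH9) and Qingxin 1 (QX1) are conventional varieties. Kucha is a bitter tea that stores the purine alkaloid theacrine. Per the labels' protocols, ribosomal RNA was depleted, and complementary DNA was made with random primers and with dUTP in the second strand, a design that keeps the strand of the transcript. The extraction text in the labels also speaks of retinas, which no other label matches, and the tissue was taken as leaf from the tissue label. The depletion and dUTP steps stand in that same text and were taken as applying, so the strand design is not certain. Nothing in the labels says whether the 3 libraries of a genotype came from separate plants, so p-values measure the spread between these libraries, which may be technical.

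The authors deposited 1 table per library with an FPKM value, per the file headers. FPKM is the number of fragments of a gene, scaled by its length in kilobases and by the mapped fragments of the library. The values carry 2 decimals. The submitters' processing notes name Bowtie2 2.2.8 and TopHat2 2.1.1. The program that computed the FPKM, the genome build, the annotation version and any filter are not given in the sources used here. Each table lists the same 42704 features, of which 33932 are annotated genes with a TEA identifier and 8772 are unannotated loci with an XLOC identifier. Only the unannotated loci carry a scaffold, a strand, a start and an end, and their listed length is the genomic span. Of all features, 3639 were listed at 0 in every library.

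The files do not pair the identifiers with gene names, and 0 of the identifiers were found among the 80110 genes of the reference table at hand. The gene lists fixed before the data were examined could therefore not be tested, and no gene function is given. By the rule for this case, 2 features that rose and 2 that fell are named. They are those with the greatest rise and fall of the Kucha mean against the conventional mean, among features called the same way in all 4 Kucha-conventional comparisons with no overlap between the 6 Kucha and the 6 conventional libraries.

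Because the deposited values are FPKM and not counts, the differences were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a trended and robust prior. Fold changes on this scale understate the change of features with low values. Features with at least 1 FPKM in at least 3 libraries were tested, which left 29364 features, 22782 of them annotated and 6582 unannotated. A single model with a mean per genotype was fitted to all 12 libraries, so that the genotypes share an estimate of the spread. Contrasts were taken for the 6 pairs of genotypes and for the mean of K6 and K11 against the mean of YH9 and QX1. A feature was called changed at a Benjamini-Hochberg adjusted p below 0.05 and an absolute log2 difference of at least 1. Features called in the same direction in K6 against YH9, K6 against QX1, K11 against YH9 and K11 against QX1 are termed shared. The same count was made for the other ways to set 2 genotypes against the other 2. These comparisons reuse libraries, so 20 data sets with no difference between genotypes were simulated, and they gave 0 shared features at most. With 3 libraries per genotype the controls could not be split into parts of at least 2, so part of any excess over independent lists may come from the shared libraries.

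The test was first run on simulated data made from the means and spread of the 29364 features, with 200 features changed in both Kucha genotypes. The 200 were drawn from features with a mean of at least 1 FPKM, so recovery below that level was not measured. In the Kucha mean against conventional mean contrast it recovered 0% of the 67 features changed 1.5-fold, which lie below the fold threshold. It recovered 88.1% of the 67 changed 3-fold and 93.9% of the 66 changed 6-fold, and it called 0.00343% of the unchanged features. For the shared set the recovery was 74.6% at 3-fold and 87.9% at 6-fold.

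Absolute depth is unknown, because the files give no counts. Low FPKM values are multiples of what 1 read is worth, which allowed an estimate of relative depth. Ratios of low values (0.12 to 1.2 FPKM) were formed between each library and K6 replicate 2. The step taken was that with the largest excess of ratios over the number expected from nearby ones, scaled by its expected spread. No interval based on read counts is given. Replicates of the same genotype shared the same value in at most 1.32% of the features listed above 0 in either of them, so none was a copy of another.

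The alternatives were a pseudocount of 0.1, no filter, a stricter filter of 5 FPKM, quantile normalization, scaling by an unweighted trimmed mean of M-values (TMM), the replicate number as a block, fits on only the genotypes compared, leaving out each library, and no fold threshold. Restriction to annotated genes and scaling of the libraries to an equal sum were added after the data had been seen, as were the pair-mean contrasts of the other groupings.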

Results

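The data comprise 12 leaf libraries from 2 Kucha genotypes (K6 and K11) and 2 conventional tea varieties (YH9 and QX1), with 3 libraries per genotype. The series was designed to compare genotypes of contrasting theacrine content. Per library, the FPKM values summed to between 609588 and 653908. The number of features with at least 1 FPKM was 24998 ± 252 in K6, 25458 ± 190 in K11, 25945 ± 121 in YH9 and 24900 ± 133 in QX1 (mean ± SD, n = 3 libraries each). YH9 had 3.29% more features of at least 1 FPKM and 7.74% more of at least 10 FPKM than the mean of the other libraries. These excesses were not recomputed under another scaling. The YH9 libraries also had the highest estimated depth. Relative to K6 replicate 2 it was 2.83, 1.51 and 1.64 for replicates 1, 2 and 3, against 0.953 to 1.27 in the other libraries. The estimate for YH9 replicate 1 was the least firm, with 51 low-value ratios at the step where 25.3 were expected. The 10 most abundant features took 8.10% ± 0.28 of the summed FPKM in QX1, 6.28% ± 0.33 in K6, 5.96% ± 0.30 in K11 and 5.39% ± 0.11 in YH9 (SD, n = 3 each). Unannotated loci held 15.9% to 17.5% of the summed FPKM per library.

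The first question was how the leaf transcriptomes of the 4 genotypes relate to each other. K6, a Kucha genotype, lay closest to QX1, a conventional variety, and not to K11, the other Kucha genotype. The Pearson correlation across the 29364 tested features averaged 0.903 between K6 and QX1 libraries (range 0.887 to 0.915 over 9 pairs of libraries). Between K6 and K11 it averaged 0.854 (0.836 to 0.864), so the ranges did not overlap. The mean was 0.849 (0.840 to 0.856) between K11 and QX1, so K6 was the nearest genotype to K11 by the mean, with overlapping ranges. YH9 had means of 0.842 (0.834 to 0.849) to K6, 0.820 to K11 and 0.828 to QX1, and the first of these ranges overlapped that of K11 and QX1. Within a genotype the mean correlation was 0.975 in K6, 0.979 in K11, 0.985 in YH9 and 0.981 in QX1. Correlations across features describe these libraries only, since features are not independent replicates. The first principal component separated YH9 from the other genotypes and held 38.8% of the variance. The second set K11 apart (32.4%), and the third separated K6 from QX1 (17.6%). On the first and second components the 2 kinds were interleaved. On the third, K11 and YH9 lay close together near 0, between K6 and QX1, with the K11 libraries just below those of YH9.

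**Figure D1:**
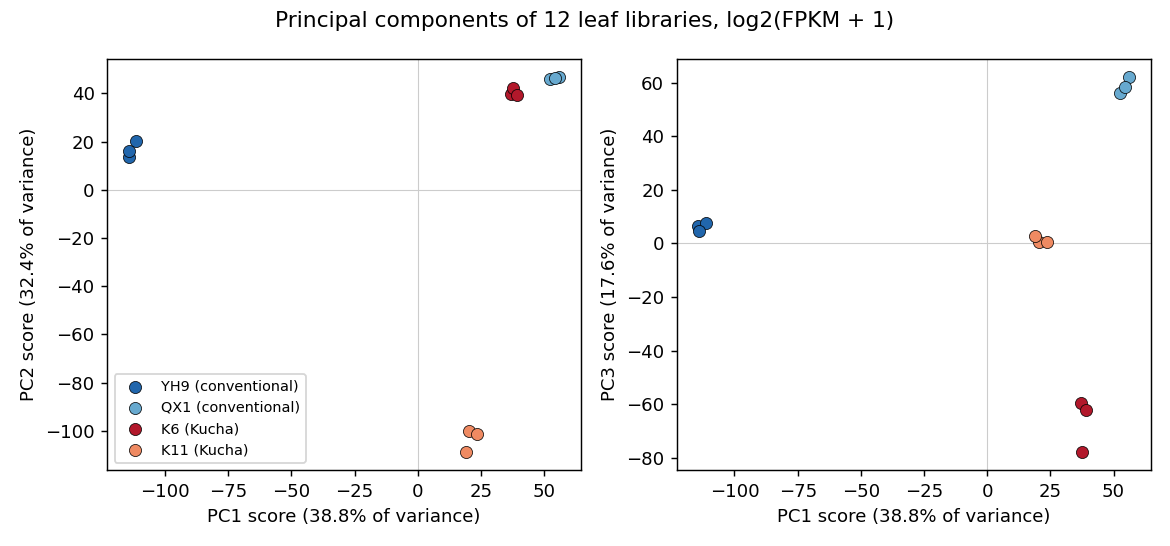
Scores of the 12 libraries on principal components 1 and 2 (left) and 1 and 3 (right) of log2(FPKM + 1) over 29364 features; the axes are unitless scores, each point is a library and colours mark genotypes. YH9 lies alone on the first component (38.8% of the variance) and K11 on the second (32.4%), while K6 and QX1 are parted on the third (17.6%).

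Each Kucha genotype was then compared with each conventional variety. K6 differed from YH9 in 6441 features, 2501 higher and 3940 lower in K6, and from QX1 in 3479 features, 1712 higher and 1767 lower. K11 differed from YH9 in 7010 features, 3039 higher and 3971 lower, and from QX1 in 5641 features, 3111 higher and 2530 lower. Calls were made with limma at an adjusted p below 0.05 and a log2 difference of at least 1. The median size of the called differences was 1.51, 1.46, 1.55 and 1.53 on the log2 scale, in the same order. Differences of at least 8-fold were found in 466, 226, 611 and 517 features. The balance of higher and lower features depended on the scaling of the libraries. The median log2 difference over all tested features was -0.15 in K6 against YH9, -0.07 in K11 against YH9, 0.08 in K11 against QX1 and 0.01 in K6 against QX1. After quantile normalization, which brings these medians to within 0.005 of 0, K6 against YH9 gave 3098 higher and 3168 lower features, so 49.4% were higher in place of 38.8%. K11 against YH9 then gave 3439 higher and 3525 lower features, and K11 against QX1 2781 and 2788. Quantile normalization itself forces such a balance. With TMM scaling, K6 against YH9 gave 2945 higher and 3326 lower features and K11 against YH9 3236 and 3660, so lower features were still the more numerous. K11 against QX1 gave 2778 and 2840, so higher features were no longer the more numerous.

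Abundant features did not follow the overall split of K6 against YH9. The abundant class held the 896 tested features with a mean above 100 FPKM over all 12 libraries. Of these, 181 were higher and 68 lower in K6 than in YH9, while below 100 FPKM 2320 were higher and 3872 lower. With quantile normalization the abundant class still held 161 higher and 93 lower features, and with TMM scaling 223 and 54. QX1 also exceeded YH9 in this class, with 197 features higher in QX1 and 94 higher in YH9. Against QX1, K11 had 63 abundant features higher and 136 lower. K11 against YH9 was more even, with 159 abundant features higher and 131 lower in K11. Between the Kucha genotypes, 161 abundant features were higher and 60 lower in K6 than in K11. K6 against QX1 had 50 higher and 41 lower. The class was chosen by a mean to which the compared libraries contribute. Features high in both K6 and QX1, which resemble each other, enter it more readily than features high in a single genotype. Whether the splits follow from this choice was not tested.

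Differences between genotypes of the same kind give the background for these counts. The 2 Kucha genotypes differed from each other in 5648 features, 2558 higher and 3090 lower in K6. The split was 2779 to 2759 with quantile normalization and 2803 to 2810 with TMM scaling. The 2 conventional varieties differed in 6994 features, 4280 higher and 2714 lower in YH9, with a median log2 difference of 0.17 over all tested features. Under quantile normalization the split between YH9 and QX1 was 3427 to 3352, or 50.6% higher in YH9 in place of 61.2%. K6 against QX1 had the fewest called features of the 6 pairs. Both within-kind comparisons thus gave more called features than K6 against QX1, a comparison between kinds.

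**Figure D2:**
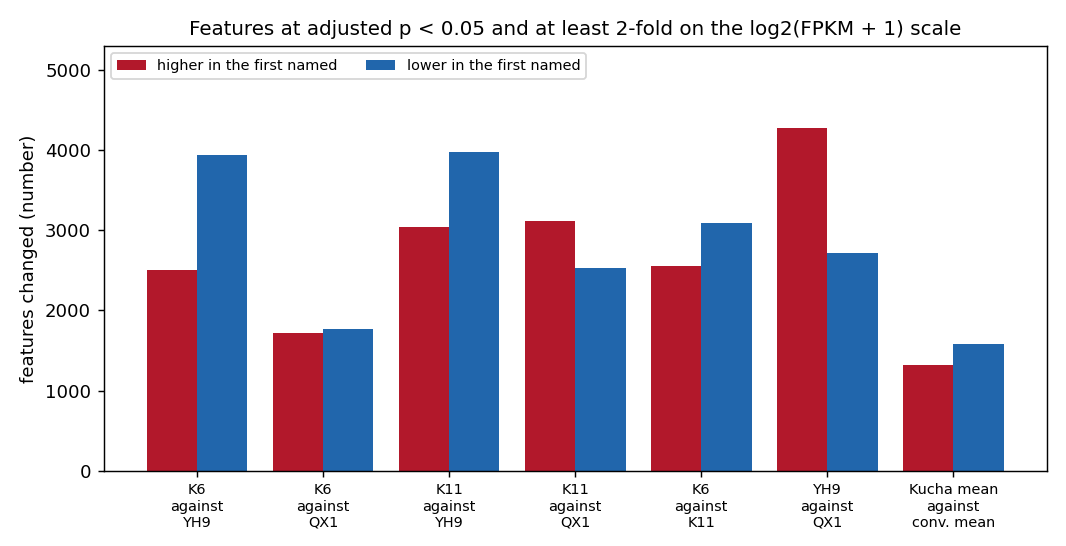
Number of features called higher (red) and lower (blue) in the first-named genotype of each comparison, by limma at an adjusted p below 0.05 and at least 2-fold on the log2(FPKM + 1) scale; each genotype has 3 libraries. K6 against QX1 has the fewest of the 6 pairwise counts (1712 and 1767), and the contrast of the kind means gives 1325 and 1584.

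The mean of the 2 Kucha genotypes differed from the mean of the conventional varieties in 2909 features, 1325 higher and 1584 lower in Kucha (1449 and 1465 with quantile normalization). Of these, 353 (12.1%) were called in the same direction in all 4 pairs of a Kucha genotype with a conventional variety. This shared set held 160 features higher and 193 lower in Kucha. Lists of these sizes drawn independently would share 1.599 higher and 2.763 lower features, and simulated libraries without any difference shared 0. Neither value gives the overlap to be expected where genotypes differ and comparisons share libraries. Part of the excess may come from the libraries that the comparisons share. The median log2 difference was 2.07 for the higher features (quartiles 1.63 and 2.54) and -1.86 for the lower ones (quartiles -2.46 and -1.55). The mean difference reached 8-fold in 18 of the higher and 23 of the lower features. In 153 of the 160 and 184 of the 193 features, all 6 Kucha libraries lay on one side of all 6 conventional libraries. Chance would give this for 0.216% of unselected features if the 12 libraries were independent, but libraries of a genotype resemble each other. The shared features were also selected for their difference between the kinds, so the figures are not comparable. Most shared features were low in the kind with less: the median level was 7.08 FPKM in Kucha against 0.607 in conventional leaves for the higher set, and 0.425 against 5.99 for the lower set. The test rests on the spread of libraries within a genotype, and only 2 genotypes stand for each kind.

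The Kucha grouping gave the fewest shared features of the 3 ways to set 2 genotypes against the other 2. K6 and YH9 against K11 and QX1 shared 395 features (221 higher, 174 lower). K6 and QX1 against K11 and YH9 shared 948 (404 higher, 544 lower). The contrast of pair means ranked the groupings the same way, with 2909, 3260 and 3956 called features. The Kucha-conventional contrast held 29.0% of the variance between genotype means, against 31.1% and 39.9% for the other groupings. The correlation of fold changes restates these shares of variance and is not separate evidence, because the sum and the difference of the fold changes correlated are themselves contrasts of the groupings. Across features, the log2 difference of K6 against YH9 correlated with that of K11 against QX1 at a Pearson r of -0.148 (Spearman rho -0.122). Among features called in both, 674 went in the same direction and 1375 in opposite directions, where independent lists would give 604 and 633. For K6 against QX1 with K11 against YH9 the Pearson r was -0.038 (rho -0.069), with 603 in the same and 688 in opposite directions, where independent lists would give 416 and 414.

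**Figure D3:**
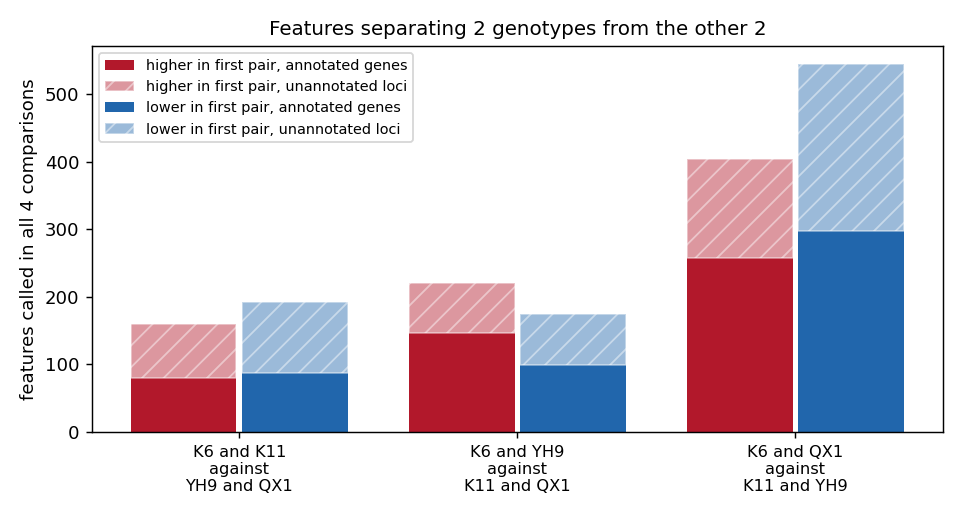
Number of features called in the same direction in all 4 comparisons between 2 genotypes and the other 2, for the 3 possible groupings; red bars are higher and blue bars lower in the first pair, and hatched parts are unannotated loci. The Kucha grouping has 160 higher and 193 lower features, and K6 and QX1 against K11 and YH9 has 404 and 544.

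A fixed rule singled out 4 features. TEA009099.1, an annotated gene, had the greatest rise in Kucha. Its level was 364 ± 129 FPKM in K6 and 650 ± 94 in K11, against 0.163 ± 0.152 in YH9 and 0.673 ± 0.525 in QX1 (mean ± SD, n = 3 each). The Kucha mean exceeded the conventional mean by 8.44 ± 0.17 (SE) on the log2(FPKM + 1) scale (limma, adjusted p = 8.01e-12). All 6 Kucha libraries lay above all 6 conventional ones, as the rule required. K11 was higher than K6 by less than the fold threshold, with a log2 difference of K6 against K11 of -0.88 ± 0.25 (limma, adjusted p = 0.0103). TEA010054.1, also an annotated gene, stood at 142 ± 9.1 FPKM in K6 and 222 ± 3.1 in K11. In YH9 it stood at 11.1 ± 3.1, and in QX1 it was listed at 0 in 2 libraries and at 0.18 in the other. Its log2 difference was 5.65 ± 0.10 (SE; limma, adjusted p = 1.31e-12).

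The greatest fall was that of the annotated gene TEA010243.1, at 0.250 ± 0.070 FPKM in K6 and 0.213 ± 0.220 in K11 against 191 ± 10 in YH9 and 18.8 ± 6.5 in QX1 (SD, n = 3 each). The log2 difference was -5.62 ± 0.15 (SE; limma, adjusted p = 3.35e-11). The unannotated locus XLOC_030709 came next, at 0.277 ± 0.151 FPKM in K6 and 0.170 ± 0.161 in K11 against 16.0 ± 0.85 in YH9 and 45.04 ± 4.5 in QX1. Its log2 difference was -4.52 ± 0.10 (SE; limma, adjusted p = 8.01e-12). It lies on the minus strand of scaffold 27998 from position 1 to 11021, in the coordinates of the deposited tables, whose build is not given in the sources used here. The difference of K6 against K11 was 0.06 ± 0.21 and 0.13 ± 0.14 (SE) for these features and did not pass the test (limma, adjusted p = 0.851 and 0.494). The files give no position for the annotated genes, and the Kucha levels of TEA010243.1 and XLOC_030709 are low, between 0 and 0.45 FPKM per library. The 4 features were picked for their large differences, and their SE and p-values measure the spread of libraries within a genotype. They do not measure the spread between genotypes of a kind: YH9 and QX1 alone differed by 3.49 in TEA010054.1.

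**Figure D4:**
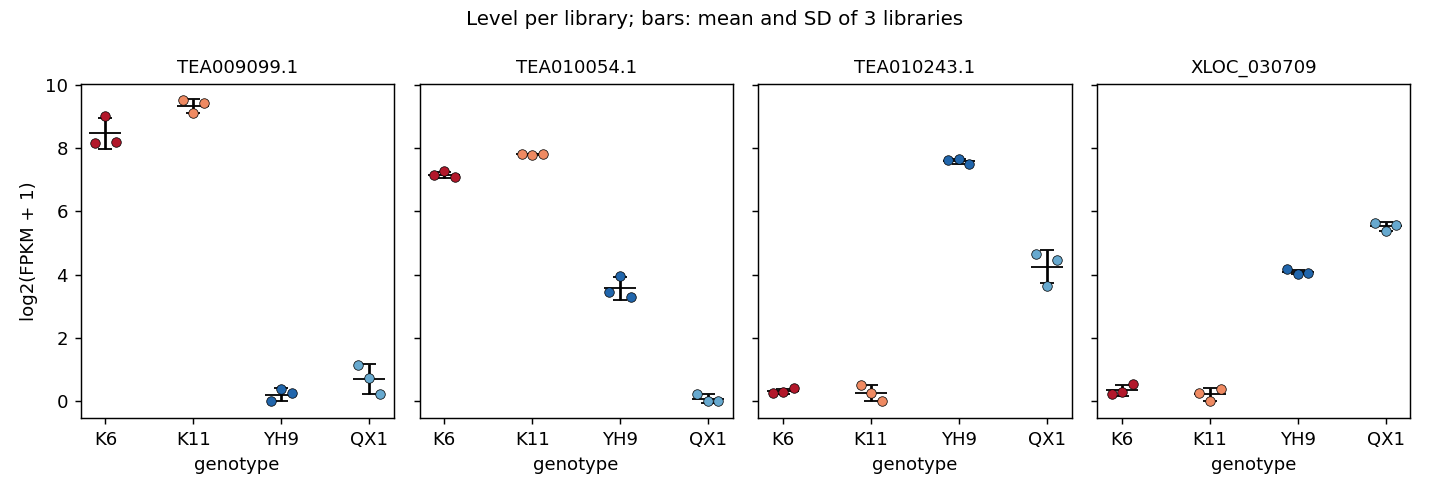
Level of the 4 named features in each of the 12 libraries, as log2(FPKM + 1), by genotype; points are libraries, and the horizontal mark and bar are the mean and SD of 3 libraries. In each panel the 6 Kucha libraries lie apart from the 6 conventional ones, as the naming rule required. YH9 and QX1 differ in 3 of the 4 panels by more than their spread.

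Features present in one kind and listed at 0 in the other were few. A set of 10 features, 9 of them unannotated loci, was listed at 0 in all 6 Kucha libraries with at least 1 FPKM in all 6 conventional libraries and means of 1.39 to 12.3 FPKM there. The reverse held for 2 unannotated loci, with means of 4.53 and 5.41 FPKM in Kucha. The other groupings gave 11 and 5 such features (K6 and YH9 against K11 and QX1) and 21 and 19 (K6 and QX1 against K11 and YH9). A value of 0 in these files can also stand for a level below the rounding.

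Unannotated loci were called more often than annotated genes in each comparison. In the contrast of kind means, 1195 of the 6582 unannotated loci (18.2%) and 1714 of the 22782 annotated genes (7.52%) were called, a ratio of 2.41. The pairwise ratios ran from 1.55 in K11 against YH9 to 2.44 in K6 against QX1. Of the 353 shared features, 52.7% were unannotated loci, with 80 in the higher and 106 in the lower set. In the other groupings the unannotated part was 37.97% and 41.4%.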

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

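Of the tests in this part, those of the groupings, of features called for both Kucha genotypes, of mixed RNA and of mislabelled libraries were chosen after the result was seen. The test for mixed RNA replaced one set down before, which was restricted to features absent from YH9 and K11 and left too few of them.

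In 354 features K6 and K11 were called in opposite directions against the mean of the conventional varieties, which implies a difference between K6 and K11; that difference was called as well in all of them, as the selection nearly ensures. K6 was the higher of the Kucha genotypes in 166 of them and K11 in 188, beside 1304 features called in the same direction for both. Both contrasts use the same conventional libraries, which favours calls in the same direction. Independent lists would share 315 features in the same and 314 in opposite directions, and unchanged simulated groups shared 0. The other groupings gave 1276 and 297 (K6 and YH9) and 2274 and 109 (K6 and QX1) in the same way, so the excess is not read as a shared Kucha effect. Among the named features, genotypes of the same kind differed by a direct test. TEA009099.1 and TEA010054.1 were lower in K6 than in K11 by less than the fold threshold, with log2 differences of -0.88 and -0.64 (limma, adjusted p = 0.0103 and 0.00224). YH9 and QX1 differed in TEA010054.1 by 3.49, in TEA010243.1 by 3.33 and in XLOC_030709 by -1.44 (limma, adjusted p = 6.57e-10, 3.06e-08 and 2.1e-06). In each of these cases the 3 libraries of one genotype did not overlap the 3 of the other.

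K6 lay nearest to QX1, and the Kucha grouping shared the fewest features. That all 3 groupings shared at least as many features as the Kucha grouping, itself included (353, 395 and 948), restates this pattern and tests nothing further. The tables argue against a mixed share of 2% or more between K6 and QX1, which would set a floor: 18 of 5697 features of at least 20 FPKM in QX1 lay below 2% of that level in K6, and 13 of 5749 in the reverse direction. All 12 libraries correlated best with a library of their own genotype, which argues against single libraries exchanged between genotypes, and in 0 of 6 alternatives of scaling, filter and pseudocount did another pair have the fewest called features. An exchange of all libraries of a genotype stays open, and a shared background of K6 and QX1 is a hypothesis that was not tested.

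Unannotated loci were called 2.41 times as often as annotated genes in the contrast of kind means. The tables argue against abundance as the whole cause, because the ratio averaged 1.86 over 10 classes of equal size by mean abundance, although it was 0.846 in the most abundant class. The ratio in the Kucha grouping was 1.15 times the higher of the other groupings, which leaves open whether part of it is tied to the kind. A candidate explanation that was not tested is that these loci include transcripts that were not expressed in the annotated cultivar. The loci have positions on scaffolds, so their sequence is present in the assembly used. How the loci were defined is not given in the sources used here.

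YH9 libraries listed the fewest features at 0, with 8580 ± 771 against 9949 ± 413 in QX1, 10230 ± 178 in K11 and 10314 ± 576 in K6 (SD, n = 3 each). If depth were the cause, an excess under 1% was predicted among features of at least 10 FPKM, and at least 5% if not; the excess was 7.74%. That prediction was badly chosen for features at 0: the level of 10 FPKM does not bear on them, and the estimated depth of each YH9 library exceeded that of every other library. Depth therefore stays open for the features at 0, while it was not predicted to give the excess at 10 FPKM. The factors of the TMM scaling were 1.07 to 1.09 in YH9 and 0.923 to 1.053 in the other libraries. Such a shift raises counts above a fixed level. The excess was not recomputed after scaling, so the scaling of the libraries stays open as its cause.

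For the contrast of kind means, 1 of 100 drawn splits of the 12 libraries into 4 sets of 3, the real one, called as many features (2909, against 1448 at most in the others). For the shared features 1 of 100 reached each count, with 160 higher and 193 lower against 70 at most in either direction in the other splits. The other splits break up genotypes whose libraries resemble each other, so their low counts show only that libraries of a genotype belong together, and they do not test Kucha against conventional. With genotypes kept whole, the 3 groupings gave 2909, 3260 and 3956 features for the contrast of means and 353, 395 and 948 shared features, so for the assignment of genotypes to kinds chance cannot be excluded. For the 6 pairs of genotypes, 10 splits of 6 libraries are too few for a share below 0.05; the real splits called 3479 to 7010 features and the other splits 2 at most.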

How the results depend on the processing

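Restriction to annotated genes, scaling to an equal sum and the pair-mean contrasts of the other groupings were chosen after the data were seen. In each of 23 settings, the main one included, the Kucha grouping shared the fewest features and K6 and QX1 against K11 and YH9 the most, and K6 against QX1 had the fewest called features of the 6 pairs. The 4 named features kept their direction and call in each setting that tested them (XLOC_030709 was not tested with annotated genes only). They had been chosen for the largest differences in these same data, so this outcome is no separate evidence. Their log2 differences ranged from 8.31 to 10.29 for TEA009099.1, 5.58 to 7.16 for TEA010054.1, -7.63 to -5.52 for TEA010243.1 and -6.55 to -4.46 for XLOC_030709, with an adjusted p of 2.31e-08 at most (limma). Counts moved by more than 1.5 times under the alternatives of pseudocount, stricter filter, fold threshold, annotated genes and grouping given here. With a pseudocount of 0.1, which shrinks low values less, the kind means gave 5511 features and the shared sets 337 higher and 336 lower. The filter at 5 FPKM leaves 19575 features in place of 29364, so its counts are out of fewer features. With that filter, the pairs K6-YH9, K6-QX1, K11-YH9, K11-QX1, K6-K11 and YH9-QX1 gave 4146, 2088, 4598, 3482, 3582 and 4460 features. The shared sets then held 110 higher and 110 lower features, where the higher set moved by less than 1.5 times. Without a fold threshold the 6 pairs gave, in the same order, 16210, 10322, 16480, 14260, 14307 and 16809, the kind means 14963, and the shared sets 812 and 709. With annotated genes only, K6-YH9, K6-QX1, K11-QX1 and K6-K11 gave 4265, 2036, 3610 and 3739, the kind means 1712, and the shared sets 79 and 86. The main fit called 4275, 2042, 3620 and 3750 annotated genes in these pairs and 1714 for the kind means. Its shared sets held 80 and 87 annotated genes, so among annotated genes the counts hardly moved. Grouping K6 with QX1 gave 404 and 544 in place of 160 and 193, and the correlation of fold changes was -0.038 for K6-QX1 with K11-YH9 in place of -0.148. The replicate numbers did not pair the libraries (0 of 18 same-numbered pairs correlated above 0.1, and 2 of 12 libraries correlated best with their own number); with the replicate block the kind means gave 2909 features and the pair K6-YH9 6433, and no other count moved by 1.5 times. Leaving out single libraries gave 152 to 176 higher and 179 to 209 lower shared features, 2886 to 2988 features for the kind means, 3412 to 3664 for K6-QX1, and a correlation of -0.158 to -0.141. The tests of gene lists were not run, since nothing pairs the identifiers with names, and the alternatives for counts do not apply to FPKM. Depth limits what can be said of features near 0, and its estimate was higher in YH9 than in the other genotypes.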

Other observations

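The counts per genotype in the next paragraph were made after the data were seen, and of the tests on neighbouring loci, those on close pairs of one strand and on opposite strands were split off after the result was seen.

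Each genotype had features that set it apart from all 3 others. YH9 had the most, with 1795 features higher and 730 lower than in each other genotype, followed by K11 with 1066 and 685. QX1 had 650 and 348, and K6 had the fewest, with 496 and 281. This order partly restates the pairwise counts, since a feature had to differ from all 3 others and K6 and QX1 differed least. Features of at least 1 FPKM in all 3 libraries of a genotype and listed at 0 in the 9 others numbered 61 in YH9, 44 in K11, 42 in QX1 and 38 in K6. Unannotated loci made up 53, 39, 28 and 29 of them. In the reverse case, listed at 0 in all 3 libraries of a genotype with at least 1 FPKM in the 9 others, K11 had the most with 42, against 20 in YH9, 12 in K6 and 9 in QX1. YH9 had the highest estimated depth, and the counts of this paragraph were not recomputed under another scaling, which levelled the split of YH9 against QX1 from 61.2% to 50.6% higher.

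A hypothesis tested on the unannotated loci, for which positions are listed, was that neighbours on a scaffold change together between the kinds. Among 1362 neighbouring pairs within 50 kb, 77 had both members called in the contrast of kind means, where permuted calls gave a median of 45 and at most 64. Of these pairs, 84.4% went in the same direction (65 of 77; permutation p = 0.001, the smallest that 1000 permutations can give; 0.0025 after Benjamini-Hochberg adjustment over 5 sets of pairs). Fragments of a transcript listed as separate loci were set down beforehand as a cause that would leave an excess only among pairs on one strand within 10 kb. The pairs on opposite strands or farther apart also went the same way in 70.3% (26 of 37, permutation p = 0.015, adjusted 0.019). Most of these pairs lay on opposite strands, so this argues against fragments as the whole cause only if the listed strands are right. Split further, close pairs on one strand went the same way in 97.5% (39 of 40; permutation p = 0.001, adjusted 0.0025), consistent with fragments for that part. Pairs on opposite strands did so in 73.1% (19 of 26; permutation p = 0.011, adjusted 0.018), and pairs on one strand over 10 kb apart in 63.6% (7 of 11; permutation p = 0.27), which did not pass. Imperfect strand assignment and regional differences between the genomes were not examined and stay open. The other groupings gave 84.8% of 66 and 76.2% of 105 called pairs in the same direction, so a shared direction of called neighbours is not particular to Kucha. The number of pairs with both members called exceeded each permutation for K6 and QX1 against K11 and YH9 (105, against 99 at most) but not for K6 and YH9 against K11 and QX1 (66, against a median of 44 and at most 71). Whether the groupings differ in that number was not tested.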
